A study of Arabidopsis thaliana with 12 samples.

How the data were processed

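The arrays measured total RNA of WT and toc160 plants, with 6 arrays per group and replicate numbers 1 to 6 in both, per the labels. The deposited table holds 1 intensity per probe and array on a linear scale, as the values show. How the authors scanned, background-corrected and scaled these intensities is not given in the sources used here. The deposited values run from 0 to a ceiling of 100, which 3 probes reach, and the mean per array lies between 1.05 and 1.11, so some scaling of the intensities by the authors came before deposit. Its form and any background subtraction remain unknown. Per array, 143 to 194 of the 3439 values were exactly 0, and 97 probes were 0 on all 12 arrays. Median intensities were 0.477 to 0.551 on WT arrays and 0.627 to 0.646 on toc160 arrays.

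Probes were named through the platform annotation supplied with the table. It gave 1 gene for 692 probes, several for 870 and none for 1877, and no gene was named from a probe with several. Of the 692, 690 matched a gene of the TAIR10.1 reference by gene identifier and took its current symbol; the other 2 kept the annotation's name. The pair of probes of 1 locus was averaged, which left 691 loci. No coordinates are given, because no genome build is stated for the arrays.

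Values at or below the 1st percentile of all positive intensities (0.0364) were raised to it before log2 transformation. Column medians differed by 0.44 on the log2 scale, above a limit of 0.1, so all 3439 probes were quantile normalized between arrays, which sets every array to 1 distribution and removes any shift common to most probes. The locus values were fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, toc160 minus WT, 6 arrays against 6 without a block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences and their SE come from this fit; means ± SD are deposited intensities over pair averages.

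The replicate numbers pair the samples. Deviations of same-numbered arrays from their group means correlated with r between 0.518 and 0.722 in all 6 pairs, and each of the 12 arrays correlated best with its own number in the other group. Within a group, replicates 1 and 2, 3 and 4, and 5 and 6 had Spearman correlations of 0.983 to 0.990, against 0.871 to 0.945 for other arrays of the group. The pairs were therefore averaged in alternatives, with and without the pair as a block. The 6 arrays of a group were kept as replicates in the primary fit, as set before the data were examined, so its p-values count near-duplicate arrays as separate samples.

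The fits were tested on simulated data for the 691 loci with 200 changed and no values at the floor. The SDs drawn were 0.226 between pairs, shared by WT and toc160, 0.236 between pairs within a group and 0.182 between arrays of a pair. As estimates from the data, that shared by the groups is too low. That within a group is too high, as it holds part of the others. All loci were given the same SDs, unlike the real loci. The shares below therefore describe the simulated setting and are not error rates for these data. The fit of 6 arrays against 6 recovered 57.6%, 95.5% and 100% of changes of 0.5, 1 and 2 on the log2 scale, and 10.1% of its calls were false. Blocking by replicate number made 16.4% false calls. Pair averages without a block made 0% false calls and recovered 10.6%, 91.0% and 100%. Pair averages with the pair as a block made 4.12% false calls and recovered 50%, 94.0% and 100%. In the real data 35 loci were at 0 on every array of at least 1 group. The prior degrees of freedom of eBayes were 0.844 in that blocked fit over all loci, 9.33 when the 52 loci with an exact 0 were left out, and 32.7 when the dimmest 25% of loci were left out. A low value means that loci differ much in variance. A high value means that the variance of each locus is drawn towards a common one.

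Before the data were examined, 21 lists of plastid-related genes with 363 entries were fixed by locus, including import components and markers of seed tissue. Probes naming 1 gene measured 18 entries in 8 lists. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01. None of the measured loci was named as another gene by the reference. The planned lists of cytosolic ribosomal and mitochondrial respiration genes needed gene descriptions, which the reference did not hold, so they were not formed. After the probe names were seen, 8 lists were added. The added list of mitochondrial respiration, with 4 genes, is not the planned one. Named genes follow a rule fixed beforehand: import components, the 10 largest rises and the 10 largest falls past the threshold whose 6 toc160 values lie on 1 side of the WT mean, and up to 3 members with the smallest p of each list with at least 3 measured, with the member furthest the other way. Other named genes and probes (photosynthesis members of short lists, members of added lists and unnamed probes) were chosen after their values were seen.

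Alternatives set beforehand were blocking by replicate number, other scalings, leaving out the dimmest 25% of loci, an intensity trend with a robust prior, an offset of 0.140 before log2, averaging replicates in 2 ways, leaving out each array, an exact rank test, a fold threshold of 2, an estimated correlation and fry. Added after seeing the data were all probes, blocked pair averages, leaving out replicates 1 and 2, 3 and 4 or 5 and 6, leaving out probes with an exact 0 (alone and with pair averages) and leaving out probes within 3 numbers of a probe with a mean above 10. Blocked fits without zeros or without the dimmest 25% of loci were added after that with all loci had been seen.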

Results

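Transcript levels were measured on 12 single-channel arrays hybridised with total RNA of Arabidopsis thaliana, ecotype Wassilevskija. Of these, 6 arrays carried RNA of the wild type (WT) and 6 carried RNA of toc160, a mutant whose plastids import proteins poorly across the outer envelope. Toc160 is an earlier name of the import receptor Toc159, which binds plastid precursor proteins at that envelope. Each array reported 3439 probes, of which 692 named a single gene and gave 691 loci. The labels state neither the tissue nor whether the replicates were separate plants. The p-values thus rest only on the spread between these samples, pooled in part over loci, and that spread may be technical. Within each group the arrays of replicates 1 and 2, 3 and 4, and 5 and 6 were close to duplicates, and values are therefore given as the mean ± SD over 3 pair averages (n = 3). The sum of deposited intensities lay between 3612 and 3681 per WT array and between 3720 and 3815 per toc160 array, and the number of arrays limits the precision.

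The comparison of toc160 with WT asked which transcripts differ when import across the outer plastid envelope is impaired. The transcript of LHB1B2, a chlorophyll-binding protein of the light-harvesting antenna of photosystem II, showed the largest fall of the named loci. Its deposited intensity was 9.05 ± 6.01 in WT and 1.85 ± 0.241 in toc160 (SD, n = 3 pair averages), and its log2 difference after quantile normalization was -1.90 (SE 0.35, limma adjusted p 0.00527). LHCB1 genes are near-identical copies, and whether this probe tells LHB1B2 from its relatives was not tested. Transcripts of the photosystem subunits PSAN and PSBY also fell. The chloroplast NAD(P)H dehydrogenase subunit NdhS and the cyanase CYN rose, by 0.86 and 0.89 on the log2 scale. With median centring these log2 differences were 0.23 (adjusted p 0.173, not passing) and 0.53 (adjusted p 0.0337). After quantile normalization, with near-duplicate arrays averaged and blocked by pair, over all loci, PSBY and CYN passed (adjusted p 0.0404 for both). LHB1B2 (0.109), PSAN (0.270) and NdhS (0.0626) did not.

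Of the 691 loci, 72 passed an adjusted p of 0.05, 34 higher and 38 lower in toc160. Among the 10 largest falls, CML30, a calmodulin-like protein, went from 1.73 ± 0.273 to 0.761 ± 0.112 (log2 difference -1.36, SE 0.12, adjusted p 2.66e-05). AT4G32060, which encodes a mitochondrial calcium uptake protein, fell from 4.89 ± 0.909 to 1.94 ± 0.328 (log2 difference -1.24). XERICO, a RING zinc-finger protein linked to abscisic acid levels, fell from 6.48 ± 1.24 to 2.66 ± 0.633 (log2 difference -1.16). CUTA, a copper-binding protein of the chloroplast, fell from 5.94 ± 0.913 to 2.64 ± 0.806 (log2 difference -1.05). The other loci among the 10 largest falls were AT4G31470 (-1.29), AT1G62250 (-1.24), AT4G05030 (-1.04), AT4G31530 (-1.01) and AT5G06990 (-1.01). AT4G31530 was the brightest of them, at 47.6 ± 8.81 in WT and 18.4 ± 5.05 in toc160.

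Among the 10 largest rises, AT2G11270 had the largest log2 difference, 2.56 (SE 0.50, adjusted p 0.00731), a size that depends on the floor. This probe was dim in WT, at 0.192 ± 0.129, and its value on WT replicate 3 was an exact 0. Without that array the log2 difference was 2.096 (adjusted p 0.000617). In the pair-blocked fit over all loci AT2G11270 did not pass after quantile normalization (adjusted p 0.103) or with cyclic loess (0.0679). It did pass that fit as deposited (0.0376) and with median centring (0.000587). AT3G09080 rose from 3.68 ± 0.668 to 7.23 ± 0.669 (log2 difference 1.22, SE 0.11, adjusted p 2.58e-05). AT4G39760 rose from 3.86 ± 1.06 to 7.15 ± 0.215 (log2 difference 1.11). NdhS rose from 8.14 ± 0.921 to 11.9 ± 0.609, and CYN from 1.80 ± 0.470 to 3.27 ± 0.868. The remaining loci were AT4G35660 (0.92), AT4G31930 (0.85), AT4G25290 (0.72), AT3G54930 (0.72) and AT2G37510 (0.71). AT4G31930 lay within 3 probe numbers of a bright probe, a position where probes with a mean under 1 varied more. Whether a probe as bright as AT4G31930 (0.922 in WT, 1.81 in toc160) also varies more there was not tested. The probes of AT3G09080 (893) and CYN (896) lie close in number, as do that of AT2G11270 (3055) and the rising unnamed probe 3057. Whether these rises are independent of position was not tested. The rule that chose these 20 loci required all 6 toc160 values to lie on 1 side of the WT mean.

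**Figure D1:**
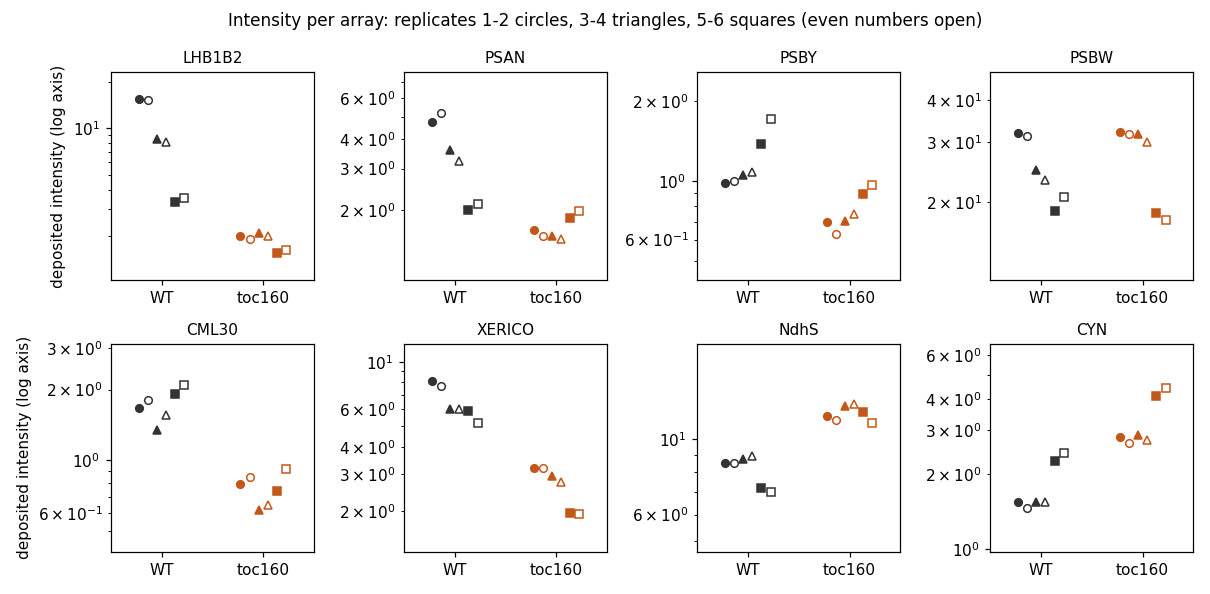
Deposited intensity (log axis) of 8 loci on each of the 6 WT and 6 toc160 arrays, each point being 1 array and the symbols marking replicates 1 and 2, 3 and 4, and 5 and 6. LHB1B2 in WT averaged 15.4, 8.34 and 3.43 in these pairs, while in toc160 it stayed between 1.58 and 2.03, and the deposited values of PSBW overlapped between the groups.

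Scaling affected the calls of both directions. Under quantile normalization, no normalization, median centring and cyclic loess alike, 9 of the 10 falls and 5 of the 10 rises passed with the same sign. AT4G05030, dim at 0.155 ± 0.0533 in WT and 0.111 ± 0.026 in toc160, passed only under quantile normalization of these 4, and its log2 difference as deposited was -0.46 (adjusted p 0.35). AT4G35660, NdhS, AT4G25290, AT3G54930 and AT2G37510 did not pass with median centring, where the log2 difference of NdhS was 0.23 (adjusted p 0.173). The rises of AT3G09080 (0.66) and AT4G39760 (0.60) passed with median centring but were smaller, and the fall of CML30 was larger (-1.51). Over all loci, 41 of the 72 calls held under all 4 scalings, 15 higher and 26 lower. The share of higher calls was 47.2% after quantile normalization, 91.1% as deposited and 23.6% with median centring, and as deposited the median log2 difference of all loci was 0.33.

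With the near-duplicate arrays averaged, the number of loci past the threshold depended on the fit. With no block, 3 loci passed. With the pair as a block 12 passed, 2 higher and 10 lower, among them CML30, AT4G31470, AT1G62250, AT4G32060, PSBY, PSBW and CYN. The same blocked fit over the 518 loci left after the dimmest 25% were removed called 116 loci, 59 higher and 57 lower, which held 62 of the 72 calls. After quantile normalization, 5 of the 20 loci listed above passed in the blocked fit over all loci. For the filtered fit 19 were bright enough, and all 19 passed there. Which loci passed over all loci depended on the scaling. XERICO (0.0842 after quantile normalization) passed as deposited (limma adjusted p 0.0211), with median centring (2.38e-05) and with cyclic loess (0.0181). NdhS passed as deposited (0.0288) and with cyclic loess (0.0435), but not with median centring (0.199). AT4G39760 passed under no scaling. LHB1B2 had an adjusted p of 0.109 in the blocked fit over all loci, or 0.00133 with median centring, and 3.87e-12 in the filtered one. The filtered p-value rests on a variance largely pooled over loci (prior degrees of freedom 32.7, against 0.844), not on the spread of LHB1B2 alone. Its log2 ratios in the 3 pairs were -2.62, -1.98 and -1.10, with an SE of 0.37 in the blocked fit over all loci. The other filtered p-values rest on the same pooling. Over the 639 loci without an exact 0 on any array, a filter that can also remove loci that fell to 0, the blocked fit called 101.

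Photosynthesis lists fixed in advance had 6 measured members, and 3 fell, 1 rose and 2 did not pass. LHB1B2 was the only measured member of the light-harvesting list. PSAN, a lumenal subunit of photosystem I, went from 3.48 ± 1.45 to 1.68 ± 0.210 (log2 difference -0.88, adjusted p 0.0307). The photosystem II subunit PSBY went from a normalized log2 intensity of 0.33 ± 0.23 to -0.54 ± 0.24 (SD, n = 3 pair averages; log2 difference -0.86, adjusted p 0.000913). PSBW, another photosystem II subunit, was higher after quantile normalization (log2 difference 0.58, adjusted p 0.00244), but the log2 difference was 0.08 as deposited, 0.19 with cyclic loess and -0.24 with median centring, none of which passed. The Calvin cycle enzyme PRK had a log2 difference of -0.65 (adjusted p 0.0554), and SBPASE one of -0.07 (adjusted p 0.862). Adjusted over the list alone, 1 of 1 photosystem I, 2 of 2 photosystem II, 1 of 1 light-harvesting and 1 of 2 Calvin cycle members passed. For a list of 1 member this is the unadjusted p, and 147 of all 691 loci had an unadjusted p under 0.05. PSAN no longer passed in either blocked fit with all loci, by replicate number (adjusted p 0.0544) or by pair (0.270), nor on leaving out WT replicate 1, 2, 3 or 4 or toc160 replicate 1, 2, 3 or 4 (adjusted p 0.0572 to 0.0697), but did in the blocked fit without the dimmest loci (2.39e-05). PRK passed in the fit blocked by replicate number (adjusted p 0.00265), with median centring (0.0247), with cyclic loess (0.0329) and in the blocked fit without the dimmest loci (2.44e-05). It did not pass in the pair-blocked fit over all loci (adjusted p 0.101), on unblocked pair averages (0.506) or as deposited (log2 difference -0.32, adjusted p 0.128). With median centring the pair-blocked fit over all loci passed PSAN (adjusted p 0.0147) and PRK (0.00798), but as deposited and with cyclic loess it passed neither. The p-values without the dimmest loci rest on variances largely pooled over loci. Because these lists had under 3 members each, they were also joined as 1 list after the probe names were seen. Against all other loci the joined list was lower by 0.65 on the log2 scale, with a camera adjusted p of 0.0726 over 8 added lists and an adjusted p of 0.228 with an estimated correlation; in the blocked fits its camera adjusted p was 0.288 over all loci and 0.00433 without the dimmest.

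Plastid ribosomal proteins and tetrapyrrole synthesis were the only fixed lists with at least 3 measured members, and no member of either passed after quantile normalization. Of the 6 ribosomal members, AT4G01310 (protein L5) had a log2 difference of 0.08 (SE 0.06), AT3G54210 (L17) of -0.15 (SE 0.13) and AT1G64510 (S6) of 0.13 (SE 0.15), and AT5G65220 was listed at 0 on all 12 arrays. As deposited, where the median of all loci was higher by 0.33, 3 of the 6 passed: AT4G01310 (0.35, adjusted p 0.00101), AT1G64510 (0.54, adjusted p 0.0157) and AT3G13120 (0.37, adjusted p 0.0171). Of the 3 tetrapyrrole members, the glutamyl-tRNA reductase HEMA3 had a log2 difference of -0.15 (SE 0.08), the magnesium protoporphyrin methyltransferase CHLM of 0.22 (SE 0.13) and the geranylgeranyl reductase AT1G74470 of -0.02 (SE 0.17). CHLM passed in the fit blocked by replicate number (adjusted p 0.0269), which counts near-duplicate arrays as separate, but not in the blocked fits on pair averages (0.201 over all loci, 0.162 without the dimmest). It also passed as deposited (log2 difference 0.45, adjusted p 0.0483) and without replicates 5 and 6 (0.29, adjusted p 0.019). In limma after quantile normalization, 0 of the 6 and 0 of the 3 passed, over all loci or adjusted over the list alone; an unadjusted p under 0.05 was reached by 0 of either, and the exact rank test called 0. The camera adjusted p was 0.961 for both lists, and 0.969 with an estimated correlation. Antioxidant proteins (2 measured) and plastid lipid synthesis (1 measured) had 0 calls too, with 0 at an unadjusted p under 0.05 and 0 by the exact rank test; as deposited, the lipid gene FATB passed (log2 difference 0.64, adjusted p 0.0011). None of the 25 listed import components, TOC159 included, was named alone by a probe, so the mutated gene's own transcript was not analysed here.

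Over all 3439 probes, named or not, limma called 528, 248 higher and 280 lower in toc160. After quantile normalization, changed probes were most frequent among bright ones. Calls by intensity were not counted under the other scalings. The 344 brightest probes, 10% of all, held 112 higher and 97 lower calls. In the blocked fit on pair averages, 43 of these 344 probes were higher, against 27 of the 3095 dimmer ones (odds ratio 16.2, p 1.33e-26), and 52 were lower, against 63 (odds ratio 8.56, p 1.72e-23). Both are two-sided Fisher's exact tests, with no allowance for the precision of bright probes or for a shift common to them. After quantile normalization the median log2 difference was still 0.173 in the brightest of 10 intensity classes, against 0.0793 in the class below. Higher calls among bright probes may rest partly on that shift, which was not tested. The unnamed probe 1439 fell from 2.21 to 0.469 (log2 difference -2.44), and probe 4061 from 4.67 to 1.46 (-1.68). Probe 1159 rose from 8.95 to 14.8 (log2 difference 1.17), and probe 3057 from 0.386 to 0.971 (1.08).

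**Figure D2:**
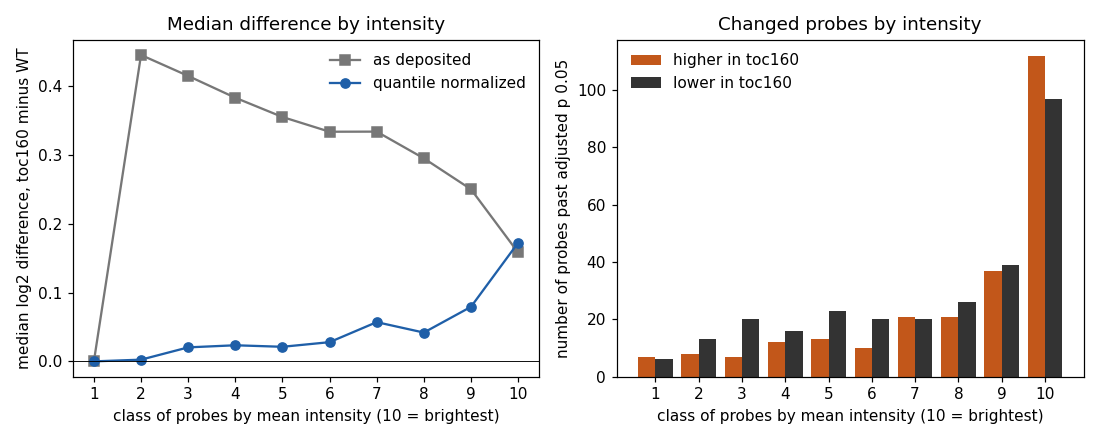
Left, the median log2 difference (toc160 minus WT) in 10 equal classes of the 3439 probes by mean intensity, as deposited (squares) and after quantile normalization (circles). Right, the number of probes past a limma adjusted p of 0.05 in each class after quantile normalization. As deposited the median difference was 0.45 in class 2 and 0.16 in class 10, the brightest. After quantile normalization class 10 had a median difference of 0.17 and held 112 higher and 97 lower calls.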

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

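The tests on neighbouring probes, on the higher median and on the WT level of LHB1B2 were chosen only after the result was seen; the test of ratio compression and the counts over other splits were set beforehand.

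Of 68 groups of 6 arrays checked for a value apart from the rest, 2 held one, and chance gives about 5%. For AT4G31530, WT replicate 3 lay at a log2 intensity of 5.62 and the other WT arrays at 5.38, with a gap of 1 times the range; quantile normalization gives arrays on which a probe holds the same rank the same value. For PSBW, toc160 replicate 2 lay at 5.21 and the nearest toc160 array at 4.93, with a gap of 0.723 times the range.

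The fall of LHB1B2 was smaller in replicates 5 and 6, with log2 ratios of -2.62, -1.98 and -1.10 in the 3 pairs. These ratios are after quantile normalization. Over the 344 brightest probes the SD of such log2 ratios in replicates 5 and 6 was 1.04 times that in replicates 1 and 2. This argues against a general compression of the normalized ratios. It cannot tell of compression on the deposited arrays, which normalization to 1 distribution would largely remove. The WT level dropped by 1.93 on the log2 scale between these pairs and the toc160 level by 0.42, a ratio of 4.62, so the difference between pairs may lie mainly in WT. What lowered the WT level remains open, as growth conditions, age and light are not in the labels. LHCB1 genes are near-identical copies, and whether this probe tells them apart was not tested.

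Deposited medians were higher on all toc160 arrays. A background of the same size added to every probe, with no other change, is argued against. In each of the 3 pairs the median gain in class 9 of 10 classes by intensity was at least 1.59 times that in class 3. A background together with a rescaling was not tested, and these ratios cannot tell of it. Scaling to a fixed total, with bright transcripts falling, could account for part: the summed brightest 5% of probes went from 1678 to 1462 and the other probes from 1967 to 2318, so the fall was 0.614 of the gain. Array sums did not overlap between groups (at most 3681 in WT, at least 3720 in toc160), so a fixed total is not the whole account, and with the scaling unknown the rest stays open. A true rise of many transcripts in toc160 is also open, as untested.

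Dim probes (mean under 1) with numbers within 3 of a bright probe (mean above 10) tended to change opposite to it. Over 118 such pairs of probes Spearman's rho was -0.317 (permutation p 0.0016), across probes that are not independent replicates, and at 10 to 12 numbers it was -0.109 (permutation p 0.26). The difference of 0.208 (bootstrap 95% interval 0.0197 to 0.399), and that of 0.287 for 4 to 12 numbers (0.141 to 0.418), argue against a response of these genes that owes nothing to position, but rho did not fade steadily: it was 0.171 and 0.242 at 6 and 7 numbers and -0.226 and -0.204 at 10 and 11, where the interval included 0 (-0.108 to 0.358). Local background or spill from the neighbouring spot is a candidate explanation, if numbers follow positions, which the labels do not say. Near bright probes 10 of 117 dim probes were over 2-fold higher in toc160, against 8 of 2570 elsewhere. Exact zeros, raised to the floor before log2, were also more frequent near bright probes (11.5% against 5.89%), so these fold changes may rest partly on the floor.

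Other splits of the 12 arrays were counted for the number of calls. Of 100 splits, 1, the real one, gave 72 or more loci, and the highest of the others gave 66; over all probes, 1 of 100 reached 528, and the highest other gave 269. Chance is excluded by these counts only if the 12 arrays are taken as separate samples, which near-duplicates are not. Among the 32 splits that part all 6 replicate numbers, the highest other gave 0 loci and 0 probes. Most of these also treat near-duplicates as separate samples, so the same limit holds for them. Of the 10 splits that keep near-duplicates together, 3 reached the real count, the real one included, so these do not exclude chance. The 2 others were higher: replicates 1 and 2 of both groups with replicates 3 and 4 of WT gave 149 loci and 740 probes, and with replicates 3 and 4 of toc160 141 and 556. These splits follow the replicate pairs, a structure of the samples that the blocked counts of 12 loci, or 116 without the dimmest 25%, take into account. The 10 splits of the pair averages are too few for a share under 0.05; the real split gave 3 loci and 76 probes, and the highest other 1 and 1.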

How the results depend on the processing

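All-probe fits, blocked pair averages and fits leaving out pairs of replicates, zeros or neighbours of bright probes were chosen after seeing the data; the cause of a change was not tested unless given. The 72 calls (34 higher, 38 lower) became 196 (105 and 91) with replicate number as a block, 292 (266 and 26) without normalization, 106 (25 and 81) with median centring and 13 (3 and 10) at 2-fold or more. Averaging near-duplicates gave 3 (1 and 2), or 6 (1 and 5) without zeros, where fewer samples enter; with the pair as a replicate block it gave 12 (2 and 10), 101 (50 and 51) without zeros, and 116 (59 and 57) without the dimmest loci. Leaving out replicates 3 and 4 of both groups gave 51 calls (27 and 24). All 3439 probes gave 528 (248 and 280), their pair averages 76 (21 and 55), with the replicate block 185 (70 and 115), and without zeros 560 (247 and 313). The other alternatives stayed within 1.5 times, and leaving out 1 array gave 58 to 71 calls, 27 to 32 higher and 30 to 40 lower. TOC159 was not run under any alternative.

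Both fixed lists kept an adjusted p of 0.455 to 0.993 throughout, and their mean log2 difference from other loci changed sign around 0. For tetrapyrrole synthesis (0.0039) it was -0.134 without normalization and with median centring, -0.0242 with loess, -0.00062 without the dimmest loci (with the replicate block too), -0.0273 without replicates 3 and 4, and -0.0109 to 0.0159 on leaving out 1 array. For plastid ribosomal proteins (-0.0166) it was 0.0015 without normalization and with median centring, 0.0073 without replicates 1 and 2, 0.0971 without replicates 5 and 6, 0.016 without zeros (with pair averages and the replicate block too), 0.0136 without neighbours of bright probes, and -0.116 to 0.0406 on leaving out 1 array. Of 256 values of added lists, 236 kept direction and side of the threshold, 13 newly passed, and 7 changed sign: pentatricopeptide repeat proteins (-0.0343 without normalization and with median centring, -0.0184 without the dimmest loci, blocked or not), assembly proteins (0.0104 without the dimmest loci, blocked or not) and fibrillins (-0.0629 without replicates 5 and 6).

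Of 922 values of named genes, 789 kept direction and side, 104 no longer passed, 16 newly passed and 13 changed sign; of these 13, PSBW alone had passed. Without normalization the log2 difference was 0.059 for HEMA3, 0.087 for AT3G54210 and 0.22 for SBPASE; with median centring it was -0.24 for PSBW. It was 0.082 for AT1G74470 without replicates 1 and 2, -0.077 for AT1G64510 without replicates 3 and 4, and 0.0012 for SBPASE without replicates 5 and 6. Leaving out 1 array gave -0.12 to 0.056 for AT1G74470 and -0.15 to 0.012 for SBPASE. AT3G54930 no longer passed without WT replicate 1 or 2 (adjusted p 0.0517 and 0.0521), and AT4G05030 on leaving out, in turn, each of 8 arrays: WT replicates 1, 3, 5 and 6 and toc160 replicates 2, 3, 4 and 6 (0.0546 to 0.0765). PRK passed without toc160 replicate 1 or 2 or WT replicate 6 (0.0138, 0.0482 and 0.0425). Signal over background limits dim probes, as 237 probes held an exact 0.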

Other observations

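Gene groups added after the probe names were seen held some calls, and most were lost in the blocked fit on pair averages over all loci. Neither is particular to these groups. Of all 691 loci 72 passed, and 11 of these 72 also passed in that blocked fit. Of 12 assembly and auxiliary proteins of photosystems, the NDH complex and other thylakoid complexes, NdhS rose (adjusted p 0.0626 in that blocked fit) and 11 did not pass. Among these 11, the values of CCB3 lay at or below the floor. Of 17 pentatricopeptide repeat proteins, which bind organelle RNA, AT3G13150 fell (log2 difference -0.49, adjusted p 0.0234, blocked 0.272), AT4G04370 rose (0.14, adjusted p 0.0121, blocked 0.146) and 15 did not pass. Of 5 mTERF proteins, AT3G46950 fell (-0.59, adjusted p 0.00989, blocked 0.0376). The histone H3 gene AT1G13370 rose (0.64, adjusted p 0.0117, blocked 0.0842); AT1G09200 did not pass (0.36, adjusted p 0.407), and AT5G65360 was listed at 0 on all 12 arrays. Without the dimmest loci, and with variances largely pooled over loci, the blocked fit called NdhS (adjusted p 1.09e-07), AT3G13150 (0.0031), AT3G46950 (6.89e-05), AT1G13370 (2.39e-05) and AT1G09200 (0.0314), but not AT4G04370 (0.391). Scaling ended some of these calls: AT3G46950 did not pass as deposited (-0.26, adjusted p 0.0872), AT4G04370 did not with median centring (0.08, adjusted p 0.494) or cyclic loess (0.12, adjusted p 0.222), and NdhS did not with median centring (0.23, adjusted p 0.173). After quantile normalization 0 of 4 fibrillins, 0 of 4 genes of mitochondrial respiration and 0 of 4 nuclear pore genes passed in limma over all loci, with 0, 1 and 2 at an unadjusted p under 0.05 and 0, 1 and 0 calls by the exact rank test. Adjusted over the list alone, 0 fibrillins, 1 respiration gene (AT4G02580, 0.0448) and 2 nuclear pore genes passed, named here after their values were seen. The 2 nuclear pore genes went opposite ways: AT1G24310 had a log2 difference of 0.28 (list-adjusted p 0.0304) and AT2G05120 of -0.21 (0.0369). As deposited, where the median of all loci was higher by 0.33, 3 of 4 were higher in each of these 3 lists, as were 7 pentatricopeptide repeat genes.

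None of the 8 added lists passed camera (the joined photosynthesis list had the smallest adjusted p, 0.0726). With fry, which tests whether the genes of a list move 1 way on balance, the joined photosynthesis list (adjusted p 0.00268) and histone H3 (0.00522) passed, the latter resting on the 2 genes not at 0 throughout. With an estimated correlation camera gave adjusted p = 0.228 for photosynthesis and adjusted p = 0.486 for histone H3. At the preset correlation the photosynthesis list passed camera without normalization (adjusted p 2.7e-05), with median centring (0.00667) and with cyclic loess (0.00615). An estimated correlation was not run under these scalings. The list also passed camera without replicates 5 and 6 (0.0107), without zeros (0.0377) and without the dimmest loci (0.0465). Leaving out 1 array gave 0.042 to 0.12, passing only without WT replicate 5 (0.0486) or 6 (0.042). Over all alternatives the adjusted p ran from 2.7e-05 to 0.288.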
